A study of Homo sapiens with 19 samples.

How the data were processed

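RNA was sequenced from 3 human lymphoma cell lines of the activated B-cell-like subtype of diffuse large B-cell lymphoma, named in the labels as OCI-LY10, TMD8 and SUDHL2. Per the labels, cells carried an inducible short hairpin RNA, a control hairpin or 1 of 2 hairpins against EGR1 (numbered 8 and 9), and received 20 ng/ml doxycycline for 2 days. The 15 RNA libraries are 9 of OCI-LY10 (3 per group), 3 with the TMD8 label and 3 with the SUDHL2 label (1 per group). The series has 19 samples, and the other 4, chromatin immunoprecipitation of EGR1 and its input, were not analysed here. Each library was placed in its group from its title and treatment label. Nothing in the labels says that the OCI-LY10 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

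The deposited tables, 1 per cell line, give 1 value per gene and library, which was read as FPKM (sequenced fragments scaled to the gene's length and to the library's size). Neither the labels nor the file headers name the unit. The reading rests on the values, which are not whole numbers, do not sum to 1 fixed total per library, and at the low end stand in ratios of small whole numbers between libraries. Per the submitters' processing notes, Bowtie2, HISAT and StringTie were used with the genome build hg19. Their versions, their roles, the gene annotation, any filter and any scaling between libraries are not given in the sources used here. The complementary DNA libraries were made with a TruSeq RNA kit, per the labels' protocols. Because the reference at hand is of another build, no coordinates are printed, and the effect of GC content and gene length was not tested.

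Gene symbols were used as the tables give them. After removal of lines with a repeated name, 25365, 25267 and 25266 genes were used in OCI-LY10, TMD8 and SUDHL2. The repeated lines (4, 10 and 10) were to be summed per symbol, but each arose from a name that had been turned into a date or split, so they were left out. The names of 26 genes per file have the form of a date. In the SUDHL2 table the line of ZZZ3 runs on into the end of the TMD8 table. The 429 lines after it equal the last 429 lines of the TMD8 table, and these lines and the joined line, 430 in all, were left out. The tables may have been normalized separately, so tests and differences were computed within a table. Levels set side by side across cell lines are descriptions only. Several HLA genes, which have near-identical copies, are listed at or near 0 in the TMD8 and SUDHL2 tables. A value of 0 can be a failed estimate, so HLA genes are uncertain in all 3 tables.

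Read totals are not given in the sources used here. Relative depth was looked for in genes under 0.08 FPKM, whose values in a pair of libraries should form ratios of whole numbers (up to 4, within 0.01 log2 units) times 1 factor per pair. In the 36 pairs of OCI-LY10 libraries 22.9 to 35.8% of such genes did so, against at most 3.4% by chance, which gives a relative depth but no counting interval. In the SUDHL2 table the share was 78.1 to 88.2% (at most 4.5% by chance). In the TMD8 table it was 86.7% between the hairpin libraries (3.5% by chance), but 9.2 and 6.5% between the control library and either of them (1.8 and 1.3% by chance). The depth of these 6 libraries was not settled.

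In OCI-LY10, a gene was tested when it had at least 1 FPKM in at least 3 of the 9 libraries, which kept 10612 genes. Values were taken as log2(FPKM + 1) and fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group and a mean-variance trend. Contrasts were each EGR1 hairpin against control, the average of the 2 hairpin contrasts, and hairpin 9 against hairpin 8. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

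Members of 27 gene lists were fixed in advance. They cover the interferon response, MYC and nucleolar genes, E2F and DNA replication, mitosis, NF-kB targets, JAK-STAT targets, B-cell receptor and MYD88 signalling, activated B-cell-like lymphoma genes, germinal centre B-cell genes, plasma cell genes, immediate early genes, p53 targets, apoptosis regulators, amino acid response, unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, MHC class I and class II presentation, ribosomal proteins, replication-dependent histones, mitochondrially encoded RNAs, and markers of T and NK, myeloid, fibroblast and epithelial, and erythroid and endothelial cells. The interferon, MYC and E2F lists were included because the study's own published account of EGR1 in this lymphoma names these programmes. Their choice is therefore not independent of the study's findings. The 23 lists with at least 3 tested members were tested with limma's camera, which compares a list with all other genes, with a preset correlation of 0.01 between genes. Camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance one way, were alternatives.

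With 1 library per group, the TMD8 and SUDHL2 tables allow no test, and their differences have no replicate check. For genes with at least 1 FPKM in 1 of the 3 libraries, log2 differences of each hairpin library from the control library were computed, and genes past 2-fold in the same direction with both hairpins were counted. The median of a list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The spread of such lists is given as the range that holds their central 95%. Short RNA genes (microRNA, small nucleolar and small nuclear RNA and similar names) were left out when cell lines were compared.

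The genes named in the text follow a rule. In OCI-LY10 they are EGR1, the 10 risers and 10 fallers with the largest average change among genes called with each hairpin in the same direction and with a group mean of at least 5 FPKM, and in each list the 2 members with the smallest adjusted p. In TMD8 and SUDHL2 they are the 8 genes furthest up and the 8 furthest down by the smaller of the 2 hairpin differences, with at least 5 FPKM in 1 library. A panel of 30 fixed genes was followed in all lines. Of the genes that meet these rules, 2 are not reported here, although counts and list results include them. The grouping, tests, lists, rule and the first set of alternatives listed next were chosen before the data were examined.

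Because both hairpins share 3 control libraries, all libraries were redrawn 50 times as independent noise around each gene's mean, with no group changed. These simulations give the agreement that arises with no effect when 2 groups share a simulated control group. The real control values were not used in them. The OCI-LY10 procedure was tested on simulated data with 200 of 10612 genes changed in each of 20 simulations. For both hairpins together it recovered 96.5% of 2-fold and 86.2% of 1.5-fold changes, and 4.5% of the calls were false. For hairpin 8 the shares recovered were 95.3 and 80.4% (4.22% false), and for hairpin 9 they were 95.2 and 78.8% (4.81% false). For calls shared by both they were 94.5 and 74.8% (0.733% false). The noise drawn was independent, had the spread of the fit and was fitted with the same model, so low false shares are almost built in. Deviations shared between genes or between same-numbered libraries were left out. These shares therefore do not tell how many of the real calls are false.

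The alternatives tried for the OCI-LY10 counts were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, array weights, a fit of only the groups compared, a minimum of 2-fold, the replicate number as a block, and each library left out in turn. For the other lines they were a pseudocount of 0.1, a filter at 5 FPKM, median-ratio scaling, a threshold of 0.58 log2 units and each hairpin alone. Chosen after seeing the data were the removal of short RNA genes, median-ratio scaling for the comparison of lines, quantile normalization and left-out libraries for the list tests, further settings for the correlation of the hairpins, and the removal of repeated names. Replicate numbers come from the titles. Whether same-numbered libraries deviated together was checked from the correlation of their deviations from the group means across genes, with 0.1 as the bound. The correlations were 0.173, 0.134 and 0.26 between the EGR1 hairpin groups, so the numbers were taken to pair these groups in the comparison of hairpin 9 with hairpin 8.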

Results

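The series asks what changes in the RNA of lymphoma cells when EGR1, an immediate early transcription factor induced by growth factor and antigen receptor signals, is targeted by short hairpin RNA. OCI-LY10, TMD8 and SUDHL2 are established cell lines of activated B-cell-like diffuse large B-cell lymphoma, a subtype driven by B-cell receptor and MYD88 signalling to NF-kB. The data are FPKM values of 15 RNA libraries, 9 of OCI-LY10 and 3 for each of the other labels. In OCI-LY10 the FPKM of a library summed to 431993 to 445028, and 10319 to 10499 genes reached 1 FPKM. The value of 1 read relative to that in control replicate 1 was 0, −0.19 and −0.17 log2 units in the controls, 0.56, 0.29 and 0.61 in the libraries labelled shEGR1#8 and −0.37, 0.28 and 0.02 in those labelled shEGR1#9, where a higher value means a shallower library. Counts behind single values are unknown. Short RNA genes took 0.471 to 0.615% of the FPKM in OCI-LY10 libraries. Under the TMD8 label they took 36.3% in the control library and 62.1 and 58.0% in the libraries labelled shEGR1#8 and shEGR1#9, and under the SUDHL2 label 54.7, 54.3 and 52.6%.

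EGR1 RNA, the target of the hairpins, was not lower in the OCI-LY10 libraries labelled shEGR1#8 or shEGR1#9. It stood at 8.57, 9.59 and 12.3 FPKM in the 3 control libraries, at 10.04, 11.4 and 20.5 in those labelled shEGR1#8 and at 10.8, 11.8 and 22.8 in those labelled shEGR1#9. The group means were 10.2 ± 1.93, 14.0 ± 5.69 and 15.1 ± 6.61 FPKM (SD, n = 3 each). The log2 difference of both hairpin labels from control was 0.42 (SE 0.267, limma adjusted p = 0.349), with 2 of 6 libraries above all controls, so the labels are not borne out by a lower level of the target. Under the TMD8 label EGR1 read 7.31 FPKM in the control library and 10.8 and 9.95 in the hairpin libraries. Only under the SUDHL2 label was it lower with both hairpin labels, at 16.9 FPKM in the control and 13.7 and 15.4 in the others (log2 differences −0.29 and −0.13, no replicate). For this reason libraries are named by their labels throughout. Every direction drawn between control and shEGR1 libraries rests on labels that the level of EGR1 does not bear out in OCI-LY10 and TMD8.

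**Figure D1:**
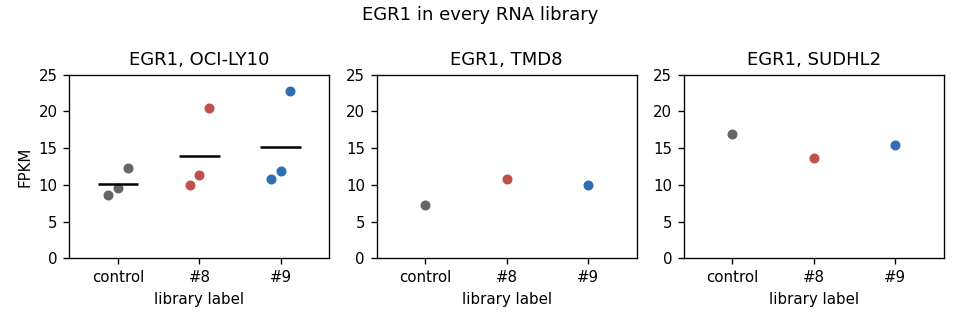
EGR1 level in FPKM (linear axis from 0) in each of the 15 libraries, by cell line label and hairpin label; points are libraries and bars are OCI-LY10 group means. In OCI-LY10 the control libraries lie between 8.57 and 12.3 FPKM and the hairpin-labelled libraries between 10.04 and 22.8.

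In OCI-LY10, 5 of the 10 largest risers in libraries labelled shEGR1#8 and shEGR1#9 belong to the interferon response list. IFI6, a mitochondrial interferon-induced protein, rose from 21 ± 0.678 FPKM in control to 74.2 ± 20.9 and 73.2 ± 13.2 (SD, n = 3 each), a log2 change of 1.73 (SE 0.177, limma adjusted p = 0.000818). IFIT1, which binds viral RNA, rose from 2.42 ± 0.196 to 7.97 ± 1.41 and 9.81 ± 0.484 FPKM. IRF7, a transcription factor that amplifies interferon production, rose by 1.33, ISG15, a ubiquitin-like modifier, by 1.24, and IFIT3 by 1.21 log2 units (limma adjusted p 0.000662, 0.00221 and 0.000184). The other large risers were IL4I1, a secreted amino acid oxidase (1.60, SE 0.092), the small heat shock protein gene HSPB1 (1.26, SE 0.221), the semaphorin gene SEMA7A (1.18, SE 0.12), the chemokine gene CCL3 (1.12, SE 0.072) and HLA-DRB1 (1.18, SE 0.158), which shares sequence with near-identical genes and is uncertain. All 6 hairpin-labelled libraries lay above all 3 controls for each of these genes. The call of HSPB1 was lost without control replicate 3 (limma adjusted p = 0.0618).

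The largest fallers in OCI-LY10 formed no single fixed list. EXOC5, a subunit of the exocyst that tethers secretory vesicles, fell from 22.9 ± 1.29 FPKM in control to 9.47 ± 1.84 and 9.60 ± 0.682 in libraries labelled shEGR1#8 and shEGR1#9 (log2 change −1.19, SE 0.106, limma adjusted p = 0.000427, n = 3 each). TAF9B, a component of transcription initiation complexes, fell by 1.00 log2 units, and WASF2, which drives actin branching, fell from 51.7 ± 0.183 to 28.0 ± 0.527 and 28.7 ± 0.492 FPKM. SKP2, the ubiquitin ligase subunit that marks the cell cycle inhibitor p27 for degradation, fell by 0.83 log2 units (SE 0.089), and PTMA, an abundant nuclear protein gene, fell from 2187 ± 57.4 to 1230 ± 53.6 and 1238 ± 116 FPKM. UBR7, the DNA repair gene NBN, SYPL1, COMMD10 and the scaffold gene IQGAP1 changed by −0.81, −0.81, −0.80, −0.75 and −0.73 log2 units, with limma adjusted p from 0.000273 to 0.00897. All 6 hairpin-labelled libraries lay below all 3 controls for each of these genes. The call of COMMD10 was lost without control replicate 2 (limma adjusted p = 0.0518).

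Across the 10612 genes tested with both hairpin labels against control, 620 rose and 288 fell (limma, adjusted p under 0.05), and 27 of these changed 2-fold or more, 23 up and 4 down. With quantile normalization 444 rose and 367 fell, and with median-ratio scaling, which moved log2 changes by −0.03 and −0.02, 533 rose and 370 fell. The count of 908 fell to 314, 315 and 285 without control replicate 1, 2 or 3 and to 534 and 539 without shEGR1#9 replicate 2 or 3. It was 1914 with array weights.

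The interferon response list rose as a group in OCI-LY10 libraries with both hairpin labels. Of its 39 tested members, 31 rose and 8 did not pass (35 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.62 (camera adjusted p = 9.22e-28, and adjusted p = 0.0111 with an estimated correlation). IFIT1 rose by 1.52 and EPSTI1, an interferon-induced gene, by 0.85 log2 units (limma adjusted p = 0.000121 for each). The antiviral genes MX1 and OAS1 rose by 0.78 and 0.44. With the labels shEGR1#8 and shEGR1#9 taken alone, 27 and 28 members rose, with medians of 0.56 and 0.67. The MHC class II list, genes of antigen presentation to helper T cells, rose with 8 of 12 members (11 adjusted over the list alone; median 0.69, camera adjusted p = 5.72e-09, and adjusted p = 0.0139 with an estimated correlation). HLA-DQA1 rose from 18.6 ± 0.194 to 38.5 ± 3.25 and 36.8 ± 1.56 FPKM and HLA-DQB1 by 0.75 log2 units, both uncertain for the copies of these genes. In the MHC class I list 1 of 12 members rose (3 adjusted over the list alone; median 0.16, camera adjusted p = 0.0614). The list passed in fry (adjusted p = 0.00972), with quantile normalization (camera adjusted p = 0.0311) and without control replicate 3 or shEGR1#9 replicate 3. HLA-B rose by 0.66 log2 units, a call lost without control replicate 2 or 3 or shEGR1#9 replicate 2 (limma adjusted p 0.0526, 0.0517 and 0.0552).

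**Figure D2:**
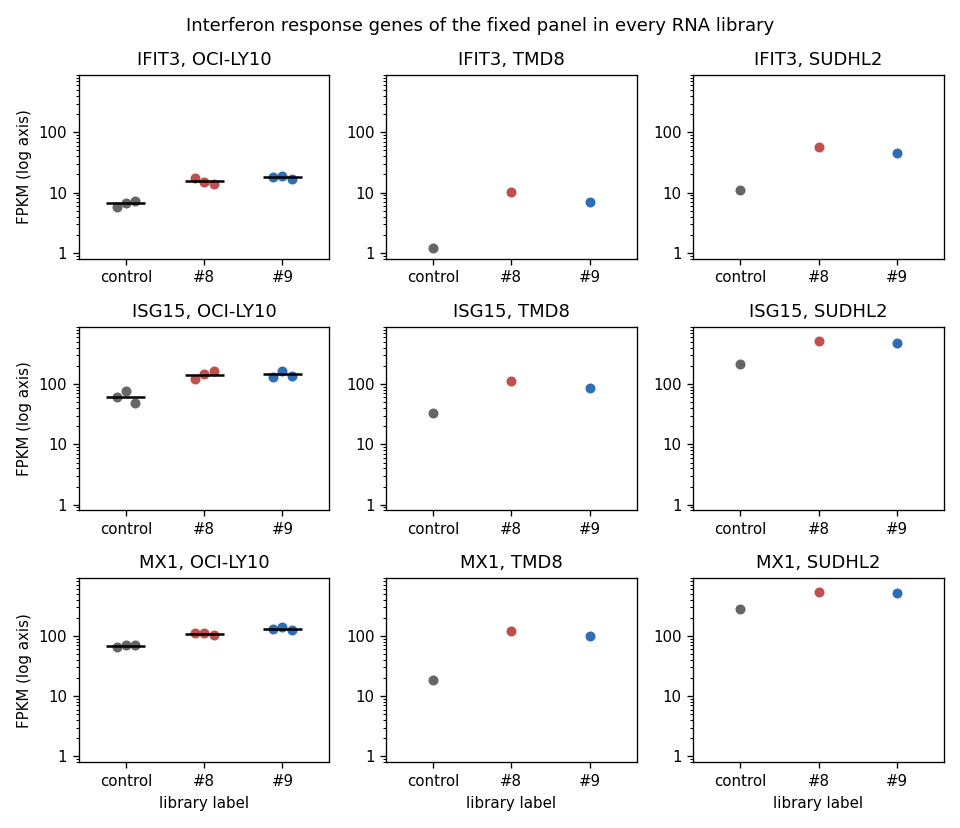
FPKM of the interferon response genes IFIT3, ISG15 and MX1 on a log axis in each library, by cell line and hairpin label. Points are libraries and bars are OCI-LY10 group means. Levels are compared only within a cell line label because the tables may have been normalized separately. IFIT3 rises in OCI-LY10 from 6.6 FPKM in control to 15.3 and 18.0.

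A few genes of growth and division fell by small amounts in OCI-LY10 libraries with the shEGR1 labels, and most members of their lists did not pass. In the E2F and DNA replication list 5 of 44 members fell and 39 did not pass (13 fell and 1 rose adjusted over the list alone), with a median of −0.09 (camera adjusted p = 2.84e-06, and adjusted p = 0.0111 with an estimated correlation). E2F2, a transcription factor of S phase entry, fell by 0.35 and ORC1, a subunit of the origin recognition complex, by 0.23 log2 units. In the MYC and nucleolar list 3 of 34 members fell (6 adjusted over the list alone; median −0.09, camera adjusted p = 4.52e-05, and adjusted p = 0.0139 with an estimated correlation), among them the ribosome assembly factor MRTO4 (−0.35) and the transferrin receptor TFRC (−0.30). In the mitosis list 2 of 40 fell (1 adjusted over the list alone; median −0.09, camera adjusted p = 7.35e-05, but adjusted p = 0.148 with an estimated correlation), TOP2A, the topoisomerase of dividing cells (−0.38), and BIRC5, survivin (−0.30). MYC itself stood at 89.9 ± 1.60 FPKM in control and 92.0 ± 11.1 and 90.2 ± 8.74 (log2 difference 0.01, limma adjusted p = 0.924), and E2F1 and the proliferation marker MKI67 differed by −0.02 and −0.04 (limma adjusted p 0.889 and 0.745). Without control replicate 1, 2 or 3 the limma adjusted p was 0.066, 0.0514 and 0.0769 for MRTO4, 0.0934, 0.139 and 0.127 for TFRC, 0.0821, 0.0643 and 0.0984 for ORC1 and 0.0776, 0.159 and 0.141 for TOP2A, and without control replicate 1 or 2 it was 0.0633 and 0.0546 for BIRC5. Left-out shEGR1#9 libraries also ended the calls of TOP2A (0.0612, 0.0825 and 0.0872 without replicate 1, 2 or 3) and TFRC (0.0701 and 0.0666 without replicate 2 or 3).

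In lists of signalling pathways more members rose than fell in OCI-LY10 libraries with the shEGR1 labels. Many did not pass, and the 4 lists lost their calls with an estimated correlation. In the NF-kB list 13 of 28 members rose, 1 fell and 14 did not pass (17 rose and 3 fell adjusted over the list alone; median 0.29, camera adjusted p = 1.08e-05, but adjusted p = 0.0942 with an estimated correlation). NFKBIE, an inhibitor of NF-kB, rose from 80.8 ± 2.37 to 120 ± 3.46 and 126 ± 2.12 FPKM, NFKBIA, another, by 0.47, and TNFAIP3, a deubiquitinase that ends the signal, by 0.30 log2 units, while the cyclin gene CCND2 fell by 0.33. In the immediate early list 8 of 26 rose, 1 fell and 17 did not pass (14 and 1 adjusted over the list alone; median 0.33, camera adjusted p = 1.08e-05, but adjusted p = 0.134 with an estimated correlation). NAB2, a corepressor that EGR1 induces, rose from 9.79 ± 0.267 to 16.2 ± 2.37 and 15.7 ± 1.60 FPKM (limma adjusted p = 0.00444), the nuclear receptor NR4A3 rose by 0.59, and EGR2 and EGR3 differed by 0.63 and 0.31 without passing (limma adjusted p 0.053 and 0.0915). EGR2 passed under 5 other settings, a replicate block, a pseudocount of 0.1, array weights and without shEGR1#8 replicate 1 or 3 (lowest limma adjusted p = 0.01). EGR3 passed with array weights and without shEGR1#8 replicate 1 (lowest 0.0413). In the JAK-STAT list 3 of 15 rose and 12 did not pass (5 adjusted over the list alone; median 0.28, camera adjusted p = 0.0245, but adjusted p = 0.134 with an estimated correlation), among them the receptor genes IL6ST (0.32) and IL10RA (0.28). In the B-cell receptor and MYD88 list 8 of 29 rose and 21 did not pass (9 rose and 1 fell adjusted over the list alone; median 0.07, camera adjusted p = 0.0499, but adjusted p = 0.194 with an estimated correlation), among them the phosphatase PTPN6 (0.63) and the kinase LYN (0.28). Without control replicate 1, 2 or 3 the limma adjusted p was 0.0784, 0.0519 and 0.0688 for TNFAIP3 and 0.0708, 0.0782 and 0.0911 for IL10RA, and without control replicate 1 or 3 it was 0.0758 and 0.0863 for IL6ST. The receptor and MYD88 list was not called with median-ratio scaling (camera adjusted p = 0.0735), or with a replicate block (0.0679). It was also not called without control replicate 2 or 3 (0.0519 and 0.0593), without shEGR1#8 replicate 1, 2 or 3 (0.0701, 0.0709 and 0.08) or without shEGR1#9 replicate 2 (0.075).

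Lists of B-cell differentiation did not pass as groups in OCI-LY10. Of 18 activated B-cell-like lymphoma genes 3 rose and 1 fell (3 and 2 adjusted over the list alone; median 0.02, turning to −0.01 with median-ratio scaling; camera adjusted p = 0.964), with the cytokine gene IL16 up by 0.45. SPIB, a transcription factor of this subtype, rose by 0.38, a call lost without control replicate 1 or 3 (limma adjusted p 0.0604 and 0.086). Of 14 germinal centre genes 1 rose and 2 fell (2 and 2 adjusted over the list alone; median −0.05, camera adjusted p = 0.451). ELL3, an elongation factor, fell by 0.41 log2 units. Of 19 plasma cell genes 1 rose (1 adjusted over the list alone), the surface receptor SLAMF7 by 0.48 (median −0.01, camera adjusted p = 0.551). IRF4, BCL6 and BATF, transcription factors of B-cell fate, differed by −0.14, 0.19 and 0.14 log2 units (limma adjusted p 0.0921, 0.306 and 0.411), and PRDM1 was below the level for testing.

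Among stress and metabolic genes, CDKN1A, which encodes the cell cycle inhibitor p21, rose from 23.4 ± 1.76 FPKM in OCI-LY10 control libraries to 49.9 ± 4.43 and 47.6 ± 2.77 (log2 change 1.03, SE 0.072, limma adjusted p = 0.000182). It was 1 of 3 risers among 20 p53 targets (5 rose and 1 fell adjusted over the list alone), with the antiproliferative gene BTG2 (0.52); the median of the list was −0.02, its mean 0.08 and its test upward (camera adjusted p = 0.991, but fry adjusted p = 0.0249). Of 26 apoptosis regulators 4 rose and 1 fell (6 and 2 adjusted over the list alone; median 0.04, camera adjusted p = 0.608, but fry adjusted p = 0.0249), with BIK, a killer of the BCL2 family, up by 0.44, a call lost without control replicate 1 (limma adjusted p = 0.0524). BCL2, BCL2A1 and MCL1, survival genes of the same family, differed by 0.06, −0.26 and −0.55 log2 units (limma adjusted p 0.508, 0.0725 and 0.363). In the amino acid response list 3 of 26 rose and 1 fell (3 and 6 adjusted over the list alone; median −0.00, camera adjusted p = 0.394), with the mTORC1 inhibitor DDIT4 up by 0.51 and CTH, an enzyme of cysteine synthesis, down (log2 change −0.67). In the unfolded protein response list 2 of 25 rose and 1 fell (2 and 2 adjusted over the list alone; median 0.04, turning to −0.01 with quantile normalization; camera adjusted p = 0.9), with HERPUD1 up by 0.43. Of 26 glycolysis and hypoxia genes 4 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.07, camera adjusted p = 0.532), with the lactate transporter SLC16A3 up by 0.88 and the peptide hormone gene ADM by 0.82. Of 30 oxidative phosphorylation genes 1 rose (1 adjusted over the list alone), with a median of 0.00, a mean of −0.02 and a downward test (camera adjusted p = 0.228). None of 24 cholesterol synthesis genes passed in limma, also adjusted over the list alone (6 at an unadjusted p under 0.05; median −0.03, mean 0.00, downward test, camera adjusted p = 0.213).

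Lists kept as checks of RNA and of other cell types gave the following in OCI-LY10. None of 48 ribosomal protein genes passed in limma, also adjusted over the list alone (9 at an unadjusted p under 0.05; median −0.05). Their list was called downward (camera adjusted p = 0.0273, but adjusted p = 0.422 with an estimated correlation and 0.221 in fry). It lost its call with a replicate block (0.051) and without control replicate 1 or shEGR1#8 replicate 2 (0.277 and 0.107), and turned upward with quantile normalization (0.798). Of 10 replication-dependent histone genes 1 fell, HIST1H1C, a linker histone, from 202 ± 11.2 to 140 ± 14.7 and 131 ± 7.98 FPKM (2 fell adjusted over the list alone; median −0.11, camera adjusted p = 0.0464, but adjusted p = 0.422 with an estimated correlation and 0.179 in fry). That list was not called with median-ratio scaling (0.0721), without control replicate 1 (0.129) or without shEGR1#8 replicate 1 or 2 (0.142 and 0.105). Of 22 T and NK cell markers 4 were expressed enough to test and 2 rose, the signalling chain CD247 from 13.8 ± 2.04 to 22.5 ± 3.00 and 22.9 ± 1.25 FPKM and the pore-forming protein PRF1 by 0.44 log2 units (4 adjusted over the list alone; median 0.38, camera adjusted p = 0.00247, but adjusted p = 0.113 with an estimated correlation). These markers moved in the same libraries as the interferon, MHC class II and NF-kB genes. The myeloid marker CD68 rose by 0.55 from 0.866 ± 0.240 FPKM, a call lost without control replicate 2 or 3 (limma adjusted p 0.0517 and 0.0558), and it was the only testable member of its list. The fibroblast and epithelial list and the erythroid and endothelial list had 1 testable member each, EPCAM with a group mean of at most 7.58 FPKM and PECAM1 with at most 5.31, and 0 of 15 mitochondrially encoded RNAs are in the table.

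Changes with the label shEGR1#8 and with the label shEGR1#9 ran in parallel in OCI-LY10. Against control, 394 genes rose and 172 fell with the label shEGR1#8, and 377 rose and 163 fell with shEGR1#9 (limma). Called with both were 297 risers, among them IFI6, IL4I1 and CDKN1A, and 116 fallers, among them EXOC5, SKP2 and PTMA, and no gene was called in opposite directions. Independent lists of these sizes would share 14.0 risers and 2.64 fallers. Simulated unchanged groups with a shared simulated control group had 0 genes in common. Independent noise gives that almost by construction, so it is no test of the real controls. Across genes, the log2 changes of the hairpin labels had Pearson r = 0.750 against a simulated 0.498, a covariance of 0.0423 against 0.0102, and the same sign in 84.3% against 66.7% of genes. Genes are not independent replicates, and part of the excess may come from the 3 shared control libraries, which are too few to split, or from same-numbered hairpin libraries deviating together (correlations 0.173, 0.134 and 0.26), which the simulation leaves out. Tested against each other, shEGR1#9 and shEGR1#8 gave 0 genes in limma (267 at an unadjusted p under 0.05), and 1, 9, 8, 1, 1 and 2 genes without control replicate 3, shEGR1#8 replicate 1 or 2, or shEGR1#9 replicate 1, 2 or 3.

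The counts per hairpin label depended on single libraries and on the fit. For shEGR1#8 the count of 566 was 136, 161 and 134 without control replicate 1, 2 or 3 and 340 and 267 without shEGR1#9 replicate 1 or 2. For shEGR1#9 the count of 540 was 168, 192 and 144 without the controls in the same order, 1143 without shEGR1#8 replicate 3, and 222, 148 and 169 without shEGR1#9 replicate 1, 2 or 3. The 413 shared genes became 117, 138 and 112 without the controls and 190, 133 and 154 without the shEGR1#9 libraries. With quantile normalization, 267 rose and 203 fell with shEGR1#8, 266 rose and 200 fell with shEGR1#9, and 205 and 141 were shared. A replicate block gave 349 genes for shEGR1#8, 351 for shEGR1#9 and 260 shared. A fit of only the groups compared gave 127, 1153 and 119, and array weights gave 749, 1950 and 693.

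**Figure D3:**
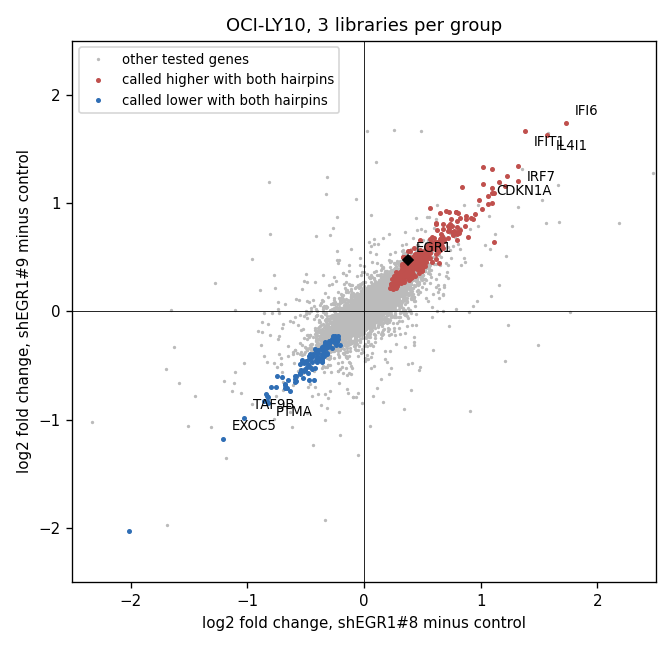
Log2 change from control on the log2(FPKM + 1) scale for each OCI-LY10 gene, libraries labelled shEGR1#8 on the horizontal and shEGR1#9 on the vertical axis, with called genes and EGR1 marked; 7 genes lie outside the axis limits of 2.5 either way. The 297 shared risers and 116 shared fallers lie along the diagonal, and the point near −2.01 and −2.03 is RAB43, chosen after its values were seen, at 3.98 FPKM in control and 0.202 and 0.180 in the hairpin-labelled libraries.

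Under the TMD8 label there was 1 library per group and no test. Of the fixed lists, those of histone and interferon genes had the highest median differences from control in the hairpin-labelled libraries. The interferon list had a median log2 difference of 1.20, above all 10000 random lists (central range −0.23 to 0.16), with 21 of 40 members more than 2-fold higher with both labels. IFI27, an interferon-induced gene, read 4.82 FPKM in the control library and 115 and 72.3 in the libraries labelled shEGR1#8 and shEGR1#9, and MX1 read 18.2, 120 and 100. Replication-dependent histones had a median of 3.38, with 16 of 20 members past 2-fold, and ribosomal proteins a median of −0.74, at the 0.03 percentile. All these differences are taken against 1 control library that stood apart from both hairpin-labelled ones, and they are not separated from what sets that library apart. Short RNA genes took 36.3% of the FPKM in the control library against 62.1 and 58.0%, ribosomal protein genes took 35.04% of the remainder against 28.3 and 26.0%, and without short RNA genes its log2 levels had r of 0.951 with either library against 0.978 between them. The genes furthest up were RPPH1 and RMRP, RNA subunits of ribonucleases (6.79 and 8.37, and 6.46 and 7.68), the small nuclear RNA gene RNVU1-19, the telomerase RNA TERC, ZNF460, the nuclear long noncoding RNA MALAT1 and POMK. Each of these genes read lower in the TMD8 control library than in every SUDHL2 library, for RPPH1 30.6 against 1974, 2235 and 3404 FPKM. Their differences therefore also rest on that 1 control library. Furthest down were H3F3A, a histone variant gene with near-identical copies (−4.94 and −4.90), FAM72D, FAM133B, DLEU2L, LYRM5, TPRKB, TICAM2 (listed at 0 with shEGR1#9) and VTRNA2-1 (listed at 0 with both). CDKN1A was higher (0.57 and 1.02) and BCL2A1, a survival gene, lower (−1.87 and −1.91).

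In all, 273 genes were 2-fold or more higher and 607 lower with both hairpin labels in TMD8. Median-ratio scaling raised the log2 differences by 0.14 for shEGR1#8 and 0.05 for shEGR1#9 and gave 297 and 456 genes. Mitosis (−0.40), E2F and DNA replication (−0.34), germinal centre (−0.26), oxidative phosphorylation (−0.45) and cholesterol synthesis genes (−0.38) had negative medians at percentiles of 1.68, 4, 4.64, 9.39 and 8.64. The MYC and nucleolar median of −0.23 lay at 69.8, so it was not low for lists of its expression level. Apoptosis regulators (0.17), immediate early (0.18) and receptor and MYD88 genes (0.04) lay at 98.9, 97.9 and 97.7. As deposited these medians were negative with shEGR1#8 (−0.04, −0.02 and −0.06) and positive with shEGR1#9 (0.19, 0.34 and 0.14), and with median-ratio scaling they were positive with both (0.08, 0.10 and 0.08, and 0.22, 0.37 and 0.18). The apoptosis median turned to −0.13 with a filter at 5 FPKM. The NF-kB median was −0.09 (−0.16 and 0.07 with the labels in the same order), at 83.4, and turned to 0.00 on the positive side with median-ratio scaling.

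Under the SUDHL2 label, again with 1 library per group, interferon genes stood higher with both hairpin labels and proliferation genes slightly lower. The interferon list had a median of 1.03, above all random lists (−0.13 to 0.08), with 19 of 40 members past 2-fold. IL4I1 read 27.0 FPKM in the control library and 250 and 181 in the hairpin-labelled libraries, and ISG15 read 217, 521 and 472. The chemokine gene CCL4 (2.15 and 2.61), the checkpoint receptor LAG3 (2.51 and 2.96), OTOF, the glycolytic enzyme ALDOC, the prostacyclin receptor PTGIR, IFIT2 and DDIT4 were also among the furthest up, and CDKN1A was higher by 1.43 and 1.52. EXOC5 was lower (log2 differences −1.03 and −1.48), as were PFDN4, PTCD1, TRAPPC2P1, SPIC, TMEM126A, FAM111B and SERPINA9. Medians above all or nearly all random lists were those of cholesterol synthesis (0.45), JAK-STAT (0.30), immediate early (0.24), glycolysis and hypoxia (0.23, or 0.12 with a filter at 5 FPKM), NF-kB (0.21) and receptor and MYD88 genes (0.21). Those of apoptosis regulators (0.16), amino acid response (0.14) and unfolded protein response genes (0.11) lay at 98.7, 99.2 and 97.4. With a filter at 5 FPKM the amino acid response median was 0.08. The 4 fibroblast and epithelial markers above the level for use, COL1A1, PDGFRB, KRT8 and CDH1, had a larger median of 0.64 at the 99.7 percentile. All 4 were higher with both labels. With a filter at 5 FPKM too few of them were left for a median, and with a pseudocount of 0.1 it was 0.985, so this value depends on low levels. The medians of E2F and DNA replication (−0.20), mitosis (−0.14), MYC and nucleolar (−0.18), ribosomal protein (−0.24) and histone genes (−0.20) lay at percentiles of 0.04, 0.96, 1.57, 0.71 and 0.64. Past 2-fold with both labels were 137 genes up and 98 down, of which 123 and 31 remained when short RNA genes were left out.

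**Figure D4:**
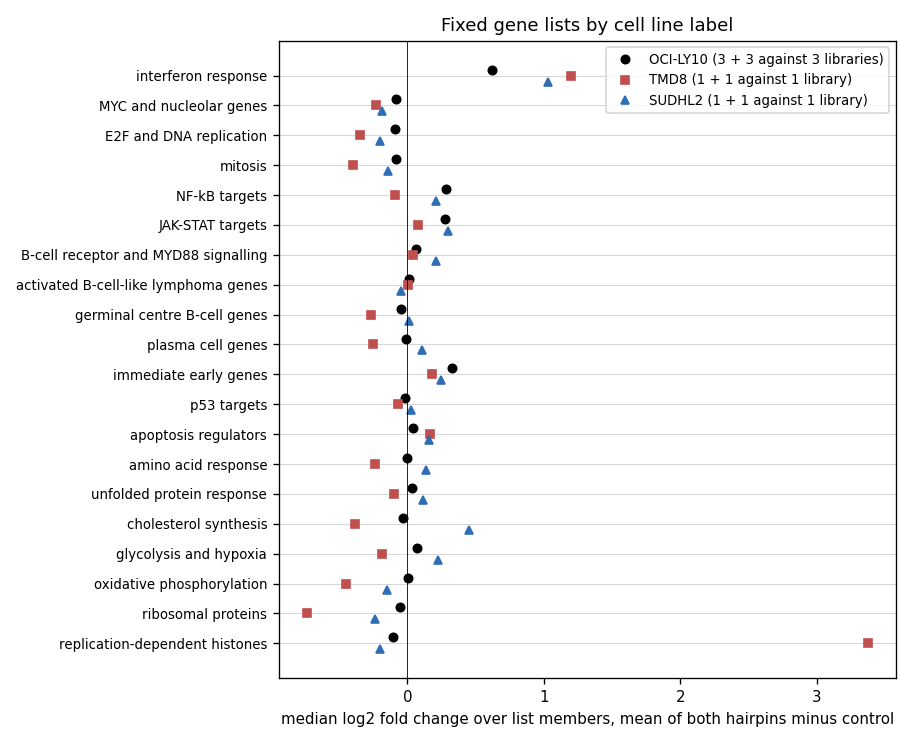
Median log2 difference from control of the fixed gene lists, by cell line label, on the log2(FPKM + 1) scale. The MHC class I, MHC class II and T and NK lists are not drawn. The MHC class II median was 0.69 in OCI-LY10 and 0.185 under SUDHL2 (92.4 percentile of random lists). Under TMD8 it was −0.25 (22.7 percentile), with −0.32 for shEGR1#8 and 0.06 for shEGR1#9. HLA genes are uncertain in all 3 tables. The interferon list is higher under all labels (0.62, 1.20 and 1.03), and the histone list stands at 3.38 under TMD8, −0.11 in OCI-LY10 and −0.20 under SUDHL2.

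Genes called in OCI-LY10 with both hairpin labels mostly differed in the same direction under the other labels. Of 381 such genes 74.8% had the same sign under the TMD8 label, where 47.2% would by the overall share of higher genes, and 88.7% under the SUDHL2 label, where 49.7% would. In all 4 hairpin-labelled libraries of these labels, 151 of 265 risers were higher (57.0%, against 18.4% of all genes) and 73 of 111 fallers lower (65.8%, against 25.6%). The risers furthest up in all of them were mostly interferon genes, such as IFIT3, IFIT1, OAS3, USP18 and IRF7, with LGALS3BP, a secreted glycoprotein, and IL4I1. The fallers furthest down were EXOC5, ATP1B3, a subunit of the sodium pump, HRSP12, the replication licensing inhibitor GMNN, FAM81A, PTMA, TAF9B and the GTPase NRAS (OCI-LY10 log2 change −0.46, limma adjusted p = 0.0113). Across genes, log2 changes in OCI-LY10 had r = 0.332 with those under the TMD8 label and 0.463 with those under SUDHL2, and the latter pair had r = 0.351.

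The libraries labelled TMD8 and SUDHL2 had near-identical expression profiles, so their results are not shown to be those of separate lines. Across 12733 genes, log2 levels of a TMD8 and a SUDHL2 library had r of 0.928 to 0.976, against 0.951 to 0.978 within TMD8, 0.9753 to 0.985 within SUDHL2 and 0.781 to 0.843 between OCI-LY10 and either. LYPD3, chosen after its values were seen, was the 1 gene with at least 10 FPKM in every library of one label and under 0.5 in every library of the other, at 13.1 FPKM or more under TMD8 and listed at 0 under SUDHL2. Between OCI-LY10 and TMD8 there were 125 such genes and between OCI-LY10 and SUDHL2 144.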

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

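Of the tests in this part, the one on scaling of the OCI-LY10 libraries was chosen before its result was seen. Those on exchanged labels, EGR1 activity, depth, hairpin RNA and the TMD8 and SUDHL2 profiles were chosen only after. Median-ratio scaling for the comparison of lines was also chosen after seeing the data.

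For 10 genes reported here and 1 list, all 6 OCI-LY10 libraries with hairpin labels lay on one side of the control mean and both hairpin-labelled libraries of another label on the other side. These differences between lines were not tested, since the other labels have 1 library per group. CCND2, a cyclin gene, was lower in OCI-LY10 (−0.41 to −0.27 log2 units per library) and higher by 1.15 on average under the TMD8 label (1.23 and 1.08). HIST1H1C, a linker histone gene, was lower in OCI-LY10 (−0.72 to −0.43) and higher by 0.68 under TMD8 and 0.39 under SUDHL2. Under TMD8 this is a shift of the whole histone list (median 3.38, 19 of 20 members higher with both labels), and all TMD8 values rest on 1 control library that stood apart from the others. Under the TMD8 label the mean differences of E2F2 (0.45), LYN (−0.36), SLAMF7 (−0.37), BCL2L1 (−0.25) and NFKBIE (−0.12) were also opposite to OCI-LY10, and that of ELL3 (0.05) under SUDHL2. Under TMD8, E2F2 was near the lowest level used, at 0.85 FPKM in the control library and 1.30 and 1.76 in the hairpin-labelled ones. NFKBIA (−0.34) and TNFAIP3 (−0.04) were lower under TMD8 as deposited, but with median-ratio scaling NFKBIA stood at −0.49 and 0.00 and TNFAIP3 at 0.08 and 0.02. That scaling kept the sign of the other genes but left NFKBIE at −0.03 and −0.03, BCL2L1 at −0.24 and −0.06, SLAMF7 at −0.09 and −0.47 and LYN at −0.25 and −0.28. The MHC class I list had a median of −0.15 under TMD8 (−0.24 and −0.06, or −0.10 and −0.01 with median-ratio scaling) against 0.11 to 0.23 in OCI-LY10. It lay at the 58.5 percentile of random lists, so it was not low for TMD8, and HLA genes are uncertain.

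EGR1 RNA was not lower in the OCI-LY10 libraries labelled shEGR1#8 and shEGR1#9. An exchange of single libraries between the control and hairpin groups is argued against, because the lowest hairpin-labelled library lies 0.463 log2 units above the highest control library in the median of the interferon list, where the largest SD within a group is 0.054. An exchange of the whole control group with 1 hairpin group stays open for those groups, since EGR1 differs by 0.424 log2 units in the direction it needs without passing, but it would leave EGR1 no lower in the other hairpin group (shEGR1#9 minus shEGR1#8 is 0.10) and so does not account for both. Under SUDHL2, EGR1 reads lower as labelled (log2 differences −0.29 and −0.13), but with 1 library per group this does not establish a lower level. The OCI-LY10 control libraries alone spread from 8.57 to 12.3 FPKM. Interferon genes are higher under SUDHL2 too, and 88.7% of the genes called in OCI-LY10 have the same sign there. Lower EGR1 activity without lower RNA may also be the case, and NAB2, which EGR1 induces, rose by 0.646 log2 units, but other EGR family members act on NAB2 and 1 target decides nothing.

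Interferon response genes were higher with both hairpin labels in OCI-LY10 and under the TMD8 and SUDHL2 labels. Scaling of the OCI-LY10 libraries is argued against as the whole cause, because the list's median stayed at 0.596 with median-ratio scaling. Lower depth of the hairpin-labelled libraries is argued against too, because shEGR1#9 replicates 1 and 3, which are deeper than the shallowest control library or within 0.02 log2 units of it, have list medians of at least 0.607. A response to hairpin RNA whatever its target may account for the rise, and it cannot be told apart from an effect of the target, since the medians of the hairpin labels differ by 0.109 and there is 1 control hairpin and no library without one. An effect of lower EGR1 stays open as the biological explanation and is not tested by an EGR1 level that did not fall.

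The libraries with the TMD8 and SUDHL2 labels had near-identical profiles. For the genes used, values copied from one table to the other are argued against, because 0 of 17217 genes above 0 hold identical values. The 429 TMD8 lines at the end of the SUDHL2 table had been left out before this count. Cells of 1 line under both labels may explain the pattern, as 1 gene, LYPD3, separates the labels by the levels used (10 and 0.5 FPKM), against 125 and 144 genes between OCI-LY10 and either label. Shared preparation of these 6 libraries was not tested, because no other line prepared with them is analysed here, and no biological explanation was tested.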

How the results depend on the processing

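Tests chosen only after the result was seen are the array weights and left-out libraries for the correlation of the hairpin labels, quantile normalization and left-out libraries for the gene lists, and the removal of short RNA genes. Of the lists called in OCI-LY10, only that of ribosomal proteins changed direction, with a median of −0.012 and an upward camera test with quantile normalization (adjusted p = 0.798). Of the lists not called, the tests of activated B-cell-like and p53 genes turned downward with median-ratio scaling and that of oxidative phosphorylation upward with quantile normalization.

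The OCI-LY10 counts of genes called rest on the spread estimate and on single libraries. With array weights the counts were 1950 for shEGR1#9, 1914 for both hairpin labels and 693 shared, and the hairpin labels had r = 0.672 (0.706 with a pseudocount of 0.1). With only the groups compared in the fit they were 127 for shEGR1#8, 1153 for shEGR1#9 and 119 shared. With a minimum of 2-fold they were 28, 22 and 27 for shEGR1#8, shEGR1#9 and both, and 17 shared. Without a filter, shEGR1#9 against shEGR1#8 gave 1 gene. The estimated correlation left 4 lists, interferon, MHC class II, E2F and MYC. Fry called 13, without the ribosomal protein and histone lists and with p53 targets, apoptosis regulators and MHC class I. Past 2-fold under the TMD8 label were 1422 genes with a pseudocount of 0.1, and 2475 at 0.58 log2 units. Under SUDHL2 these were 450 and 708, and 154 without short RNA genes. With hairpin 9 alone, 85% of OCI-LY10 calls had the same sign under SUDHL2. A stricter or looser threshold changes a count by construction, and for the other settings the cause was not tested. The fit of only the groups compared has no value for both hairpin labels against control.

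With 1 library left out, the counts ranged from 134 (without control replicate 3) to 696 (without shEGR1#8 replicate 2) for shEGR1#8, and from 144 (control 3) to 1143 (shEGR1#8 replicate 3) for shEGR1#9. They ranged from 285 to 1312 for both and from 112 to 506 for shared genes (control 3 and shEGR1#8 replicate 3), from 0 to 9 for shEGR1#9 against shEGR1#8, and from 9 to 13 for lists. The correlation ranged from 0.673 to 0.783 and the EGR1 difference from 0.27 to 0.56, without passing. Of 67 genes called among those that meet the naming rule, none changed sign and 0 to 16 lost the call with 1 library left out. A minimum of 2-fold ended the calls of 54, and each other setting ended at most 2. Calls were gained by EGR2 under 5 settings, by the interferon gene IFI27 under 3 (lowest limma adjusted p = 0.0166), by EGR3 and BCL2A1 under 2, by IRF4 with array weights, by FAM133B without shEGR1#8 replicate 1 and by SOCS3, MCL1, TPRKB and TRAPPC2P1 without shEGR1#8 replicate 2.

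The replicate number as a block (replicate block) gave 349 genes for shEGR1#8, 351 for shEGR1#9 and 260 shared, of which 328, 332 and 248 were called the same way without it, and 775 for both. It ended the calls of the receptor and MYD88 list (camera adjusted p = 0.0679) and the ribosomal protein list (0.051). It gave 0 for shEGR1#9 against shEGR1#8, where the numbers pair the libraries, and so changed no call there. Between control and shEGR1 groups same-numbered libraries share only a number, with correlations of −0.188 to 0.06, and 5 of 9 libraries correlated best with their own number. Depth limits genes near 1 FPKM most, but without read counts its size is unknown.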

Other observations

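Of the tests in this part, the counts over splits were chosen before the result was seen, except the draw of 3 groups for both hairpin labels, which was added after the count over 84 splits.

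Further genes of the fixed panel differed between the labels, given as values since TMD8 and SUDHL2 have 1 library per group. IL10, a cytokine that activates JAK-STAT signalling in these lymphomas, read 100 FPKM in the TMD8 control and 49.3 and 63.7 in the libraries labelled shEGR1#8 and shEGR1#9, and 57.4, 61.4 and 77.7 under the SUDHL2 label. SOCS3, a feedback inhibitor of that pathway, read 30.6, 56.0 and 54.9 under SUDHL2 and 37.5, 46.5 and 55.9 under TMD8. IRF1, an interferon-induced transcription factor, read 1.70, 4.27 and 3.69 under TMD8 and 3.65, 6.85 and 11.4 under SUDHL2, while in OCI-LY10 it differed by 0.15 log2 units (limma adjusted p = 0.131). MKI67, a marker of dividing cells, read 42.1, 79.1 and 65.9 under TMD8 and 69.8, 61.8 and 64.8 under SUDHL2. BCL2 read 14.5, 10.6 and 9.70 under SUDHL2 and 20.5, 23.8 and 22.6 under TMD8. CD79B, a chain of the B-cell receptor, read 177, 104 and 161 under TMD8 and 133, 122 and 132 under SUDHL2.

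MCL1, a survival gene, spread widely within 1 OCI-LY10 group, at 48.2 ± 39.2 FPKM in the libraries labelled shEGR1#8 against 86.3 ± 4.39 in control and 86.9 ± 3.93 in those labelled shEGR1#9 (SD, n = 3 each).

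Whether groups of libraries put together at random give as many genes was weighed through other splits of the same libraries. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For shEGR1#8 against control, 1 of the 10, the real one, gave 566 genes and the highest other gave 4, and for shEGR1#9, 1 of 10 gave 540 and the highest other 2. For shEGR1#9 against shEGR1#8, all 10 gave at least the 0 of the real split, with 11 as the highest other, and the 4 splits that part all 3 same-numbered pairs gave 0 each. For both hairpin labels against control, 2 of 84 splits gave as many as 908 genes. Chance is not excluded by this count, since the splits take the libraries as exchangeable, although same-numbered hairpin libraries deviate together. The highest other split gave 1404 genes, more than the real one. That split sets shEGR1#8 replicate 3 and shEGR1#9 replicates 2 and 3 against the rest, and another that sets shEGR1#8 replicates 1 and 3 and shEGR1#9 replicate 3 apart gave 792. In both, shEGR1#8 replicate 3 and shEGR1#9 replicate 3 fall on the same side, as they do in the next highest (86 and 62 genes). These are the same-numbered libraries with the highest correlation of deviations (0.26) and those with EGR1 at 20.5 and 22.8 FPKM. Control replicate 3, at 12.3 FPKM, is also the highest of its group in EGR1. In the splits with 1404 and 792 genes the true control libraries stay together as 1 group. Those counts thus also carry the difference between control and hairpin labels and do not isolate replicate 3. Whether replicate 3 differs from the rest was not tested. Of 100 drawn splits into 3 groups of 3, 1, the real one, gave as many as 908 (highest other 33). Likewise, 1 gave as many as the 413 shared genes (highest other 6). These draws held neither the split with 1404 genes nor that with 792. Few splits of these libraries thus reach such counts. A chance difference between cultures is not excluded, since the libraries of a group may not come from separate cultures.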
